A study of Mus musculus with 4 samples.

How the data were processed

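Fast-ATAC libraries of Lin-Sca1+cKit+ bone marrow cells from 4 mice were used, 2 wild type and 2 Helios null, 10 weeks old; per the labels, each library is a separate mouse. Per the submitters' processing notes, bcl2fastq 2.17.1.14, Bowtie2 2.3.4.3, HOMER, DESeq and the mm10 build were used, with no role stated for each. The peak caller, and whether peaks were called on pooled reads, are not given in the sources used here. The deposited table holds a common set of 130941 peaks, of 73 to 2933 bp, with an assigned gene name and an annotation class for each. Per the file headers, the values of each library are raw counts per peak, in whole numbers with no normalization. The deposited baseMean is a signal, the mean of the counts after the authors' size factors. The authors' fold change and its standard error are log2 values of Helios null over wild type, and whether the fold change was shrunk is not given in the sources used here. The authors' table also holds a p-value and an adjusted p-value, the latter present for 54782 peaks with a baseMean of at least 96.7 and absent for 76159.

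Counts as deposited were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Peaks were kept with filterByExpr by group, which left 130754 and dropped 187. Library sizes were scaled by TMM (factors 1.01 and 0.966 for wild type, 1.00 and 1.02 for Helios null). Genotype was tested with glmQLFit and glmQLFTest, 2-sided, with a Benjamini-Hochberg adjusted p under 0.05. Fitted fold changes used the default prior count of edgeR. A prior count of 2 was used for log2 CPM values, such as the differences within library numbers and the principal components. Values per group are TMM-normalised counts (CPM), as mean and SD over 2 libraries. Total counts per library ran from 16033211 to 30290804. Intervals and floors cover counting error only, and the floor is 3 counts over the group. The design, the tests, the gene lists and the rule for named peaks were chosen before the data were examined.

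The peaks named are every Ikzf2 peak; the 10 largest fold changes in each direction among peaks past the test with non-overlapping groups and at least median abundance, 1 per gene; 5 in each direction by the same rule at promoters; and in each gene list the 4 genes with the smallest p. Where fewer peaks passed, those with the smallest unadjusted p filled the number and are given as values that did not pass. Further peaks, such as the remaining ones past the test and peaks called in the deposited table, were chosen after their values were seen. The deposited table gives no distance to a transcription start, so its promoter-TSS class stood for promoters and the distance to the nearer end of the assigned gene stood for the distance to a start.

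The 18 gene lists were megakaryocyte and platelet, erythroid, lymphoid, granulocyte and monocyte, stem cell, NF-kB inflammation, JAK-STAT, interferon, aged stem cell, Notch, Polycomb, NuRD and Ikaros family genes, and as other cell types mast cell and basophil, B cell, T and NK cell, stroma and endothelium, and mature myeloid genes. A list held every tested peak assigned to a member. It was tested with camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists, and again with an estimated correlation and with fry. Annotation classes and distance bins of called peaks were compared with the other tested peaks by Fisher's exact test, 2-sided, adjusted over classes and directions. Gene density was the number of protein-coding RefSeq genes within 0.5 Mb.

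Alternatives were DESeq2 size factors, total counts, loess offsets, promoter factors, no filter and a stricter filter, replicate number as a block, autosomes only, middle peak widths, each library left out, limma-voom, DESeq2 1.42.0, an absolute log2 fold change of at least 1, and, for lists, peaks within 10 kb, 1 peak per gene and an estimated correlation. Gene density offsets, libraries thinned to equal depth, chromosome 1 left out, promoter peaks only for lists, DESeq2 with the block, subsets of the megakaryocyte list, random lists of peaks matched by deciles of gene density and mean signal, and class tests of the DESeq2 calls against the peaks that DESeq2 adjusted were added after seeing the data. The labels do not say that a number marks a shared litter or day. Y-linked counts showed that number 1 was male and number 2 female in both genotypes, and deviations of same-numbered libraries from their group means had a correlation of 0.335 across peaks. The block on replicate number is therefore also the term for sex, but number 1 was also the deeper library in both genotypes. The block cannot tell sex, depth and other differences between the numbers apart. Replicates differed by more than counting error (chi-square per degree of freedom 8.30 in wild type and 5.13 in Helios null), so they are not copies of each other.

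The tests were tried on simulated data. Among 130754 simulated peaks, 100 changed 2-fold and 100 changed 4-fold, all drawn from peaks of at least median abundance. Of these, edgeR recovered 32% and 98% with 8 false calls, and with the block 29% and 97% with 7. A simulated list of 150 peaks shifted by 0.5 log2 had a camera adjusted p of 1.12e-26, and 0.11 with an estimated correlation, and 0 of 20 unshifted lists were called. A list that does not pass with an estimated correlation may therefore still be shifted. Most real lists had an estimated correlation above the preset value, and no correlation between peaks of a list is stated for the simulation. The 20 unshifted lists therefore do not give the rate of false calls for the real lists. Tables and figures were made with the R package data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Motifs in changed peaks and GC correction need a genome sequence and were left out, since none was used here.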

Results

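Open chromatin was measured with fast-ATAC, an assay in which a transposase inserts sequencing adapters into accessible DNA, in Lin-Sca1+cKit+ cells sorted from the bone marrow of mice 10 weeks old. This fraction is rich in blood stem cells and early progenitors. There were 4 libraries, 2 from wild-type mice and 2 from mice that lack Helios, the Ikaros-family transcription factor encoded by Ikzf2. The common peak set held 130941 regions of the mouse genome (build mm10), with a median width of 404 bp. Counts over these peaks totalled 29745812 in wild type 1, 16033211 in wild type 2, 30290804 in Helios null 1 and 22433714 in Helios null 2. Peaks at the Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y held 1715 counts in wild type 1 and 1166 in Helios null 1, against 5 in wild type 2 and 2 in Helios null 2. Library number therefore followed sex in both genotypes, with 1 library per sex and genotype, so differences within a sex are values with no test. Number 1 was also the deeper library in both genotypes, so a term for library number cannot be read as sex alone.

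Ikzf2 locus accessibility was examined because Ikzf2 is the targeted gene. Ikzf2 lies on chromosome 1 (start 69531214, end 69687245), and 9 peaks were assigned to it. The most accessible of them covers the promoter (chromosome 1, start 69687010, end 69688027). It held 40.5 ± 10.9 normalised counts (CPM) in wild type (SD, n = 2) and 23.1 ± 1.28 in Helios null (SD, n = 2), with both null libraries below both wild-type libraries. This difference did not pass the test over all peaks (log2 fold change -0.80, SE 0.22, edgeR adjusted p = 0.189). Within each sex the log2 fold change was -0.56 for number 1 and -1.0 for number 2. The distant-promoter peak (start 69688855, end 69689310) held 17.0 ± 1.05 and 15.2 ± 0.457 CPM (SD, n = 2 each), and the other 7 peaks held between 0.578 and 4.50 CPM in wild type and did not pass either. The promoter difference passed when library number was a term of the model (log2 fold change -0.78, edgeR adjusted p = 9.86e-05). Without wild type 1 its log2 fold change was -1.07. It was -0.24 (edgeR adjusted p = 0.477) once a trend with local gene density was removed. Which part of Ikzf2 was deleted is not given in the sources used here, so a peak that remains in the null libraries does not bear on the genotype.

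Which sites change when Helios is missing was asked over all tested peaks. Of 130754 tested peaks, 8 passed: 7 fell, all on chromosome 1, and 1 rose, on chromosome 19. The deepest loss was at the intergenic peak assigned to the predicted gene Gm26342 (chromosome 1, start 67397732, end 67398540), with 209 and 163 counts in wild type and 0 in both null libraries. It was at least 145-fold lower, against a floor of 3 counts over the null group, which is 0.0563 CPM (adjusted p = 0.0034). The peak that rose is assigned to Gm24252 and lies in an intron of Dock8, a guanine nucleotide exchange factor of immune cells (chromosome 19, start 25123042, end 25123802). It went from 1.74 ± 0.0812 to 12.1 ± 0.0442 CPM (SD, n = 2 each; log2 fold change 2.79, SE 0.28, adjusted p = 0.015), and by 2.70 and 2.78 within the sexes.

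The other peaks that fell lie on either side of Ikzf2. The peak of Gm28055 (chromosome 1, start 51671156, end 51671840) fell from 13.2 ± 0.889 to 0.465 ± 0.145 CPM (SD, n = 2 each; log2 fold change -4.84, SE 0.34, adjusted p = 0.0028). The peak of Gm28980 (start 64448593, end 64449147) fell from 8.94 ± 1.33 to 0.482 ± 0.0646 (log2 fold change -4.18, SE 0.34, adjusted p = 0.0044). The peak of Gm15180 (start 75565437, end 75566117) fell from 6.89 ± 2.04 to 0.279 ± 0.0248 (log2 fold change -4.58, SE 0.41, adjusted p = 0.0079). Of the 2 peaks of Gm25832, one (start 66881731, end 66882315) fell with a log2 fold change of -5.78 (SE 0.53, adjusted p = 0.0083) and the other (start 66868211, end 66868518) with -4.80 (SE 0.48, adjusted p = 0.015). Near Lancl1, a gene for a glutathione-binding protein, a peak (start 67047884, end 67048120) held 63 and 41 counts in wild type and 0 and 1 in the null libraries. Its wild-type level was 121 times the null level, with an exact 95% counting interval of 21.3 to 4843 (adjusted p = 0.040).

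The concentration on chromosome 1 was counted after these values had been seen. Among peaks with at least 1 CPM in wild type, 20 were at least 10-fold lower in Helios null by the ratio of group means, and 0 were as much higher. Of these 20 peaks, 16 (80%) lie on chromosome 1, which holds 6.92% of tested peaks (Fisher's exact test, 2-sided, odds ratio 54.0, p = 1.01e-15). They extend from 51671156 to 126110390, and they make up 0.535% of the 2988 tested peaks in that span. The other 4 are on chromosomes 3, 6, 15 and 16.

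**Figure D1:**
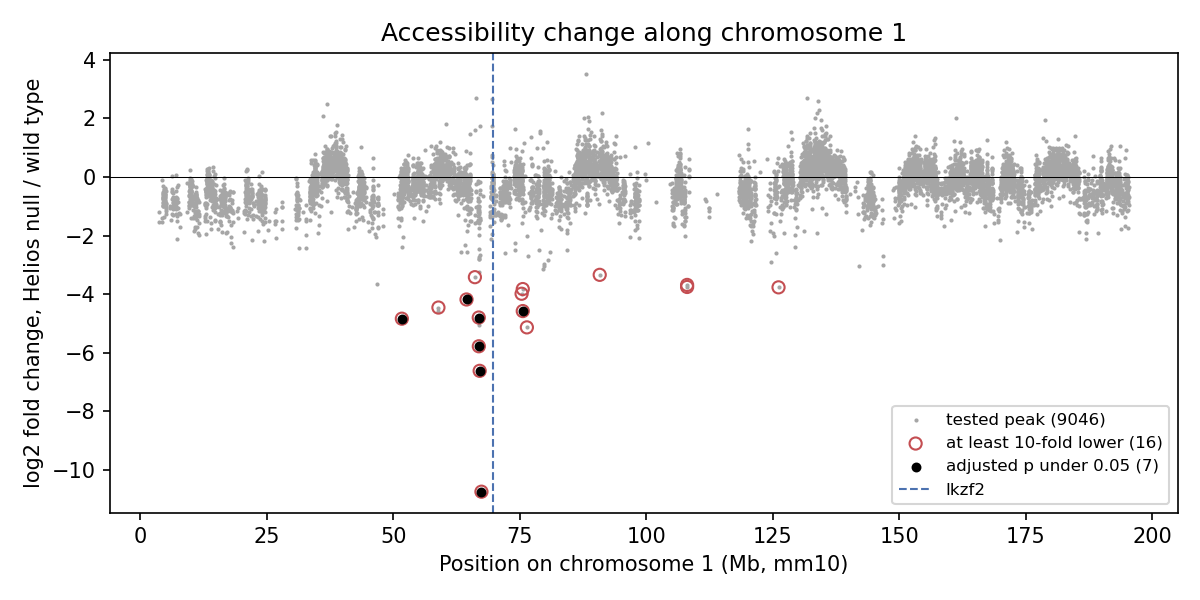
Accessibility change at the 9046 tested peaks of chromosome 1. The horizontal axis is the position in Mb (mm10) and the vertical axis the log2 fold change of Helios null over wild type; the 16 peaks at least 10-fold lower (circles) and the 7 that passed (black) lie on both sides of Ikzf2 (dashed line), and the lowest point, Gm26342, is a fitted value that depends on the prior count.

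Beyond these 8 peaks, differences were widespread and mostly small, with a median absolute log2 fold change of 0.39 over all tested peaks. An unadjusted p under 0.05 was found at 25888 peaks, 19.8% of those tested where 5% would be expected by chance, and an adjusted p under 0.2 at 12059 peaks, 4464 higher and 7595 lower. Both null libraries lay above both wild-type libraries at 28.0% of peaks and below at 28.3%, where chance gives 16.7% each. With library number, which follows both sex and depth, as a term, edgeR called 30595 peaks (13795 higher, 16800 lower), the 8 among them. DESeq2 without that term called 994 (313 higher, 681 lower) and left all 8 without an adjusted p. With that term DESeq2 adjusted 4 of the 8 and called 3, and limma-voom adjusted all 8 and called 4. Without wild type 1, wild type 2, Helios null 1 or Helios null 2 in turn, edgeR called 27955, 1021, 39 and 2078 peaks, each time including the 8.

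The named sites that did not pass were chosen by the smallest unadjusted p, not by the size of the difference. Those higher in Helios null included an intergenic peak assigned to Nos2, the inducible nitric oxide synthase (chromosome 11, start 78886811, end 78887855). It held 1.53 ± 0.942 CPM in wild type and 9.27 ± 1.76 in Helios null (SD, n = 2 each; log2 fold change 2.69, SE 0.40, adjusted p = 0.189). An intron of Fbxo31, a ubiquitin ligase subunit, held 12.9 ± 4.77 and 40.2 ± 7.32 CPM. Peaks of Prrc2b, Gm43413 (in an exon of Rhof), Gm21839 (in Rhbdd2), Gm25280 (in Pla2g5), Gabbr2, Pinx1 and Kat5 had log2 fold changes between 1.51 and 1.81. Those lower included another Lancl1 peak at 22.5 ± 3.92 against 4.07 ± 1.46 CPM (log2 fold change -2.48, edgeR adjusted p = 0.055). An intron of Serpinb10, a leukocyte serine protease inhibitor, held 19.1 ± 5.89 against 4.72 ± 0.663 CPM (-2.01). Peaks of Gm29069 (-5.13), Gm2691 (-2.57) and Gm37393 (-1.71) were lower too. Of these lower peaks, only that of Gm2691, on chromosome 6, lies off chromosome 1.

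At promoters the platelet receptor gene Gp1ba stood among the higher sites, with 15.5 ± 1.98 CPM in wild type and 35.7 ± 9.44 in Helios null (SD, n = 2 each; log2 fold change 1.20, SE 0.23, adjusted p = 0.189). The promoters of Phldb1, Hsd17b14 and A530010L16Rik had log2 fold changes of 1.44, 1.29 and 1.28. On the lower side, the promoter of the adenylate cyclase gene Adcy2 held 37.4 ± 8.65 and 15.9 ± 2.3 CPM, and that of Lancl1 42.7 ± 15.5 and 15.5 ± 4.12. The stress kinase gene Mapkapk2 (-1.84), the pseudogene Smarca5-ps (-1.68) and the kinase gene Speg (-1.58) completed this group, in which the edgeR adjusted p was 0.189 throughout. Of these lower promoters, those of Lancl1, Speg and Mapkapk2 lie on chromosome 1, as Ikzf2 does.

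The deposited comparison of the same libraries, which is not independent evidence, called more sites. In the authors' deposited table, an adjusted p under 0.05 was given to 774 peaks, 249 higher and 525 lower. All 774 peaks called in the authors' deposited table had the same sign in the edgeR fit and an unadjusted p under 0.05 there. Of the 8 peaks that passed here, 4 had an adjusted p in the authors' deposited table, and all 4 were called in it. Several genes carried more than one called peak in the authors' deposited table: Gbe1, the glycogen branching enzyme, had 6 lower peaks, Fbxl7 and Selenop 4 lower peaks each, and Gse1 4 higher peaks. In the authors' deposited table, a set of 3 higher peaks each belonged to Cbfa2t3, a transcriptional corepressor, and to Zfpm1, the GATA1 cofactor known as FOG1. Across peaks, which are not independent replicates, the fold changes of the authors' deposited table and of edgeR had a Pearson correlation of 0.815 and a Spearman correlation of 0.954.

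Gene lists were used to ask which lineage programmes differed in accessibility. Peaks of megakaryocyte and platelet genes rose as a group. The list covered 229 peaks of 29 genes, with a median log2 fold change of 0.33, and 153 peaks were above 0 (camera adjusted p = 1.08e-05, and adjusted p = 0.548 with an estimated correlation). With an estimated correlation a simulated shift of 0.5 log2 did not pass either (camera adjusted p = 0.11), so not passing there does not argue against a shift. Within the sexes the median of the megakaryocyte list was 0.41 for number 1 and 0.22 for number 2. Both null libraries lay above both wild-type libraries at 111 peaks (48.5%) and below at 36 (15.7%), against 28.0% and 28.3% over all tested peaks, where chance gives 16.7% each. Without Helios null 1 the median of the list was 0.16. By gene, the median was above 0 for 23 of the 29, among them Gp1ba at 1.11, the platelet integrin gene Itgb3 at 0.84 over 19 peaks, Gfi1b at 0.80, Zfpm1 at 0.77 over 21 peaks and Gata1, the master regulator of the lineage, at 0.71. The median was below 0 for 6 genes, among them Mmrn1, a platelet adhesion protein, at -0.76, Cavin2 at -0.54 and Arhgap6 at -0.48 over 22 peaks.

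Among the sites of this list with the smallest p, an intronic Zfpm1 peak (chromosome 8, start 122308991, end 122309933) held 6.75 ± 1.60 CPM in wild type and 19.3 ± 8.86 in Helios null (SD, n = 2 each; log2 fold change 1.53, adjusted p = 0.189). A distant-promoter peak of Itgb3 (chromosome 11, start 104596185, end 104597136) held 3.73 ± 0.481 and 8.82 ± 1.43, and one at Gata1 (chromosome X, start 7971156, end 7971814) 1.36 ± 0.274 and 3.82 ± 0.842. No peak of the list passed over all tested peaks, and 10 peaks, each of them higher, passed when adjusted over the list alone. With edgeR 61 peaks of the list were higher and 12 lower at an unadjusted p under 0.05. DESeq2 called 4 peaks of the list, all higher, and the authors' deposited table called 7, all higher.

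**Figure D2:**
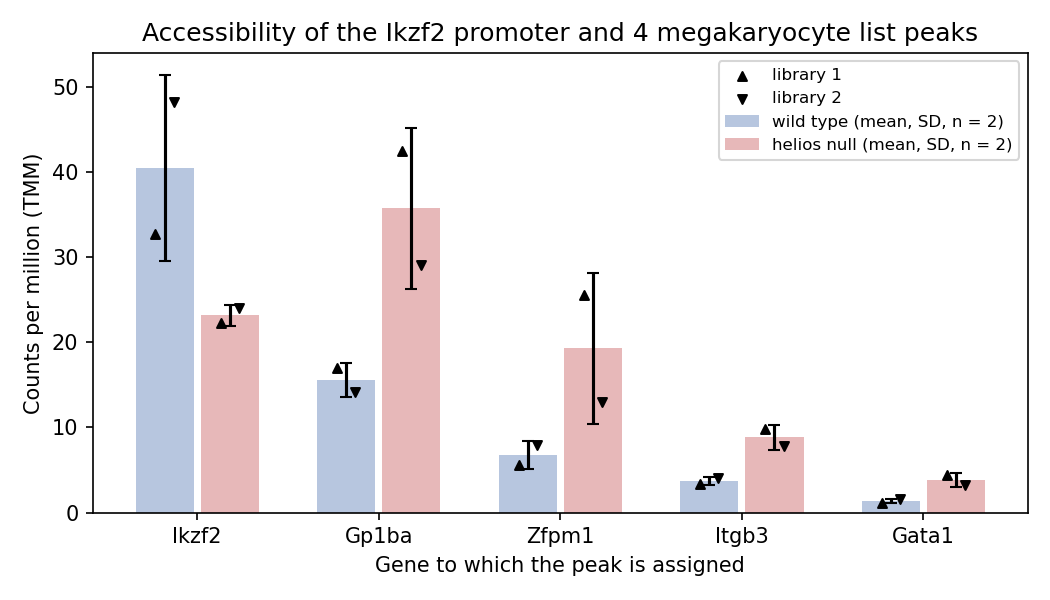
Accessibility of the Ikzf2 promoter and of 4 peaks of megakaryocyte list genes. Bars are group means in TMM-normalised CPM with SD (n = 2), and triangles are the libraries; the Ikzf2 promoter mean is 40.5 in wild type and 23.1 in Helios null, while the Gp1ba means are 15.5 and 35.7.

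Granulocyte and monocyte genes, cytokine signalling genes, Polycomb genes and genes linked to aged stem cells also rose as groups. The granulocyte and monocyte list had a median log2 fold change of 0.42, with 102 of 122 peaks above 0 (camera adjusted p = 2.68e-07, and adjusted p = 0.548 with an estimated correlation). In it the promoter of Mpo, the neutrophil myeloperoxidase gene, held 8.20 ± 4.29 CPM in wild type and 17.2 ± 2.14 in Helios null, and a peak of Cebpe, a granulocyte transcription factor gene, 31.0 ± 4.07 and 56.8 ± 12.5 (SD, n = 2 each). Irf8 had a peak at a log2 fold change of 1.17, while Csf2ra, which encodes the GM-CSF receptor alpha chain, lay lower at 97.1 ± 20.3 and 61.0 ± 4.55 CPM. The JAK-STAT list had a median of 0.29, with 147 of 189 peaks above 0 (camera adjusted p = 7.98e-07, and adjusted p = 0.548 with an estimated correlation). Its signal transducer Stat3 and its feedback inhibitor Socs3 had medians of 0.81 and 0.82 over 14 and 13 peaks. Peaks at Bcl2l1 and Pim1 had log2 fold changes of 1.06 and 0.76. Without wild type 2 the medians of gene list granulocyte_monocyte and gene list jak_stat were 0.27 and 0.19, and without wild type 1 that of gene list jak_stat was 0.44.

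The Polycomb list had a median of 0.38, with 97 of 127 peaks above 0 (camera adjusted p = 5.07e-05, and adjusted p = 0.548 with an estimated correlation). Its members went different ways: peaks of Ezh1, a histone methyltransferase, had a median of 0.69 and those of Kdm6b, which removes the same methyl mark, 0.56, while the promoter of the Polycomb subunit gene Phc1 held 41.4 ± 15.4 CPM in wild type and 20.04 ± 2.88 in Helios null. The aged stem cell list had a median of 0.26, with 119 of 177 peaks above 0 (camera adjusted p = 0.0023, and adjusted p = 0.548 with an estimated correlation), and it shares 5 genes with the megakaryocyte list. A peak of Nupr1 held 12.01 ± 1.19 and 23.1 ± 3.40 CPM, Neo1 and Tgm2 had medians of 0.79 and 0.36, and Jam2 (-0.79) and Runx1t1 (-0.92) lay below 0. The median of gene list polycomb was 0.62 without wild type 1, 0.21 without wild type 2 and 0.22 without Helios null 1, and with promoter peaks only it was 0.10 (adjusted p = 0.996). That of gene list aged_hsc was 0.14 without Helios null 1. With 1 peak per gene only the megakaryocyte (adjusted p = 0.012) and granulocyte and monocyte (adjusted p = 0.032) lists passed, and without wild type 1 the aged list no longer did (adjusted p = 0.074). Adjusted over the list alone, 0 peaks passed in these 4 lists with edgeR, where 28, 42, 25 and 32 peaks were higher and 2, 1, 4 and 12 lower at an unadjusted p under 0.05; DESeq2 called 1, 1, 0 and 2 higher and 1 lower, the latter in the Polycomb list.

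Lists of other cell types, most of which a sort for lineage-negative cells should remove, moved as well. The mast cell and basophil list (median 0.43, 36 of 40 peaks above 0, camera adjusted p = 4.23e-04), the B cell list (0.23, 36 of 51 peaks, adjusted p = 0.016) and the stroma and endothelium list (0.20, 84 of 123 peaks, adjusted p = 0.010) rose. The mature myeloid list fell, with a median of -0.35 and 18 of 57 peaks above 0 (camera adjusted p = 0.0055), and the adjusted p of all 4 lists was 0.548 with an estimated correlation. In the mature myeloid list a peak of the macrophage receptor gene Marco had a log2 fold change of -1.62. It lies within the chromosome 1 span of the lost peaks. That of Siglech, a plasmacytoid dendritic cell receptor, had -0.99, and that of Retnlg, a neutrophil product, -0.84, whereas a peak of Mmp9 lay at 0.78. Adjusted over the mature myeloid list alone, 7 of its peaks were lower and 1 higher. For the other rising lists, named single peaks were Cma1 (0.91), H2-Aa (0.93), Pdgfrb (0.73) and Col1a1 (1.49), against Cr2 (-1.73) and Lepr (-1.07). Without wild type 1 the medians were 0.68 for gene list other_mast_basophil, 0.38 for gene list other_b_cell and 0.35 for gene list other_stroma_endothelium, and without wild type 2 they were 0.23, 0.15 and 0.13. Without Helios null 1 that of the mast cell and basophil list was 0.18. The call was lost without wild type 1 for the mature myeloid list (adjusted p = 0.063), without Helios null 1 for the B cell list (adjusted p = 0.061) and without wild type 2 for the stroma list (adjusted p = 0.053).

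**Figure D3:**
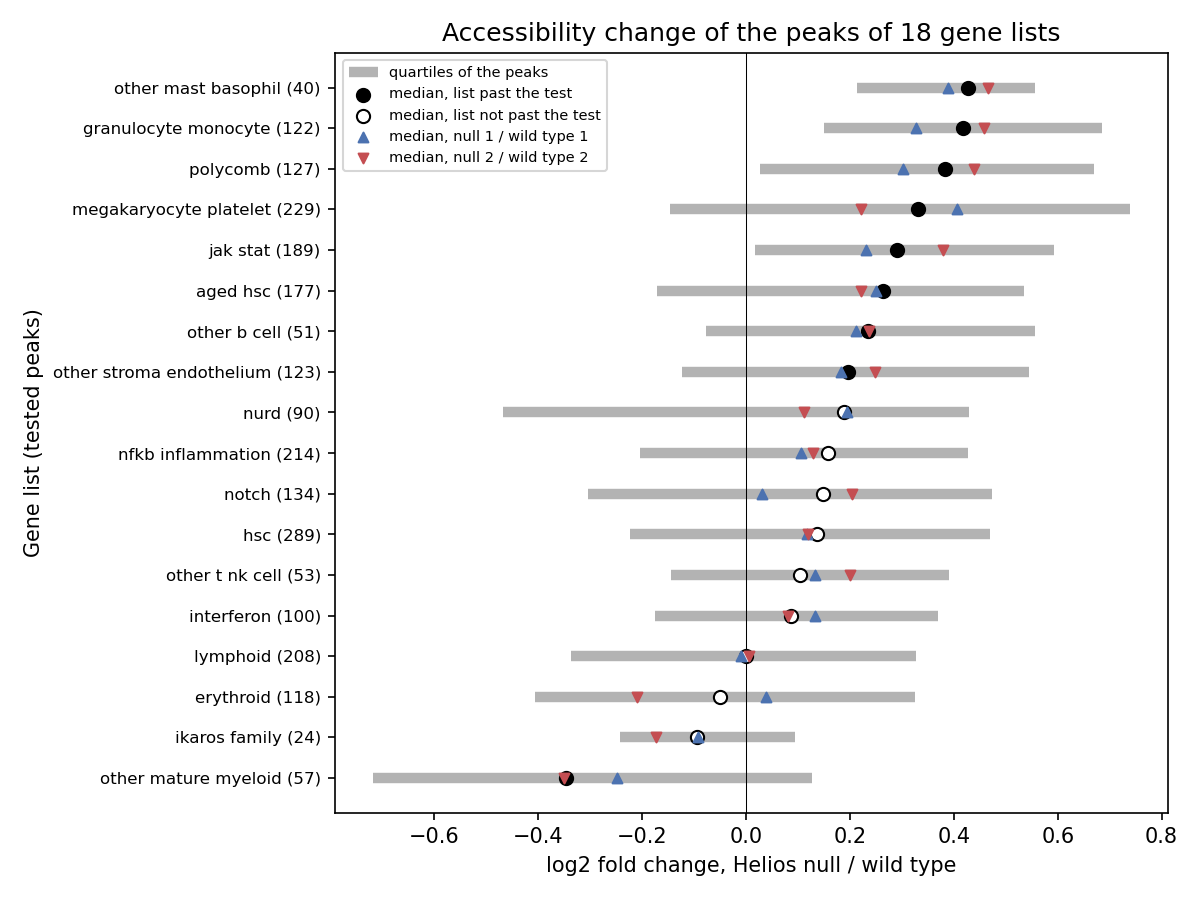
Accessibility change of 18 gene lists, with the number of tested peaks of each in parentheses. Circles are median log2 fold changes of Helios null over wild type (filled where the list passed the camera test), grey bars run between the quartiles of the peaks and triangles are the medians within each library number; the medians run from -0.35 for mature myeloid to 0.43 for mast cell and basophil genes.

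Stem cell, erythroid and lymphoid genes did not pass as groups. The stem cell list had a median of 0.14 over 289 peaks (camera adjusted p = 0.064), with peaks of the transcription factor genes Erg at 44.7 ± 5.48 against 74.4 ± 17.4 CPM, Egr1 at a log2 fold change of 0.65 and Hoxb5 at 1.01. The erythroid list had a median of -0.05, a mean of 0.0074 and a camera direction of lower (adjusted p = 0.998), and within the sexes its median was 0.04 for number 1 and -0.21 for number 2. Its members were split, with peaks of Aqp1 (1.44), Rhd (1.33) and Hemgn (0.72) above 0 and of Rhag (-1.05) below. The lymphoid list had a median of 0.00085 over 208 peaks (adjusted p = 0.731), with the B cell factor gene Ebf1 at 4.26 ± 0.0072 against 2.01 ± 0.422 CPM and the T cell factor gene Tcf7 at 2.95 ± 1.52 against 7.32 ± 1.96; peaks of Tcf3 and Ccr7 lay at 0.99 and 1.03. The T and NK cell list had a median of 0.10 (adjusted p = 0.155), with a peak of Cd3d at 0.56.

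Inflammatory and chromatin regulator lists did not pass either. The NF-kB list had a median of 0.16 (camera adjusted p = 0.060), with the Il1b promoter at 0.505 ± 0.291 against 3.01 ± 1.91 CPM. Single peaks, those with the smallest p of their gene, had log2 fold changes of 1.27 at Tnip1, 0.79 at Rela and -1.13 at Nfkbiz. The NF-kB list passed with library number as a term (camera adjusted p = 0.045), but not once the trend with gene density was removed, where its median was smaller. Its median depended on the library left out. It was higher without wild type 1 or Helios null 2, lower without wild type 2, and almost gone without Helios null 1. The interferon list had a median of 0.09 (camera adjusted p = 0.066), with single peaks of Oasl2 at 1.09, Irf7 at 1.10, Irf1 at 0.90 and Ifitm3 at 0.80. The Notch list had a median of 0.15 (camera adjusted p = 0.104), with a single peak of Mfng, a modifier of Notch, at 1.24. Single peaks of the ligand genes Jag1 and Dll1 and the target gene Hey1 lay at -0.91, -1.24 and -0.92. The medians of the stem cell, interferon and Notch lists also depended on the library left out. The stem cell median was lower whichever library was left out, and lowest without wild type 1. The interferon median was lower without Helios null 1 and higher without any other library. The Notch median was higher without wild type 1 and lower without any other library, and lowest without wild type 2.

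Genes of the NuRD complex, the chromatin remodeller that Ikaros proteins bind, showed no common direction. The NuRD list had a median of 0.19, a mean of -0.023 and a camera direction of higher (adjusted p = 0.767). Its histone deacetylase gene Hdac2 (chromosome 10, start 36973821, end 36975554) held 103 ± 34.3 CPM in wild type and 53.3 ± 8.92 in Helios null (SD, n = 2 each; log2 fold change -0.95, adjusted p = 0.189). A peak of Mbd2 had a log2 fold change of -1.68, the Rbbp7 promoter -0.74 and a peak of Chd3 1.08. Adjusted over the list alone, 4 peaks were lower and 0 higher, and the authors' deposited table called 2 peaks of this list, both lower, at Hdac2 and Mbd2. The Ikaros family list had a median of -0.09 over 24 peaks (adjusted p = 0.537), with promoter peaks of Ikzf1, Ikzf3 and Ikzf5 at -0.41, 0.50 and -0.24. With fry, which asks whether the peaks of a list move one way on balance, 0 of the 18 lists passed, the lowest adjusted p being 0.188 for the mature myeloid list, and the adjusted p for change in either direction was 0.219 for each list.

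The kinds of sites that differed were then described. Of the 7 peaks that fell, 5 are intergenic (71.4%, against 19.9% of tested peaks; Fisher's exact test, 2-sided, adjusted p = 0.091) and 2 are distant-promoter peaks. None of the 20 class and distance tests passed with the edgeR calls, where 1 had an unadjusted p under 0.05. With the DESeq2 calls against all tested peaks 14 passed, and 18 passed with library number as a term in edgeR. Against only the peaks that DESeq2 adjusted, a background chosen after the data were seen, 16 passed. In the authors' deposited table, promoter peaks made up 35.0% of the lower calls and 11.6% of the higher calls, against 24.2% of the adjusted peaks (Fisher's exact test, odds ratios 1.70 and 0.411, adjusted p = 1.59e-07 and 3.16e-06). In the authors' deposited table, distant-promoter peaks made up 8.19% of the lower calls and 30.9% of the higher calls, against 20.8% (odds ratios 0.338 and 1.71, adjusted p = 5.71e-14 and 3.79e-04). Over all tested peaks the median log2 fold change was -0.14 for intergenic peaks, 0.08 for distant-promoter peaks, 0.14 for peaks at transcription ends and 0.016 for promoter peaks.

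Regions poor in genes and regions rich in genes differed in opposite directions, a pattern noticed after the data were seen and given as values. Peaks with 3 or fewer protein-coding genes within 0.5 Mb had a median log2 fold change of -0.51, and peaks with over 20 such genes 0.33. The medians within the sexes were -0.39 and -0.58 for the gene-poor peaks and 0.24 and 0.42 for the gene-rich peaks. Gene-poor peaks held 11.2% and 14.2% of the counts of the wild-type libraries and 9.16% and 10.4% of those of the null libraries. Once each library's trend with gene density was removed, the megakaryocyte list still passed (median 0.22, adjusted p = 1.36e-04), the stem cell list passed (median 0.27, adjusted p = 2.27e-05), the B cell list no longer did (adjusted p = 0.799), and the medians of the T and NK cell, Notch and NuRD lists turned to -0.09, -0.0097 and -0.02. The medians of other lists became smaller, at 0.21 for granulocyte and monocyte, 0.21 for Polycomb, 0.15 for aged stem cell and 0.25 for mast cell and basophil genes. Each list was also set beside random lists of single peaks matched on gene density and mean signal, which ignore that peaks of 1 gene go together. The B cell median lay at percentile 40.5 of its random lists, whose middle value was 0.26, so it was no higher than matched peaks. The megakaryocyte median lay at percentile 100 (middle value 0.085), the erythroid median at 0.15 and the mature myeloid median at 0. Percentile 100 was also reached by the stem cell, JAK-STAT, aged stem cell, Polycomb, and stroma and endothelium lists. The granulocyte and monocyte list and the mast cell and basophil list lay just below it. This position was therefore not particular to the megakaryocyte list.

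**Figure D4:**
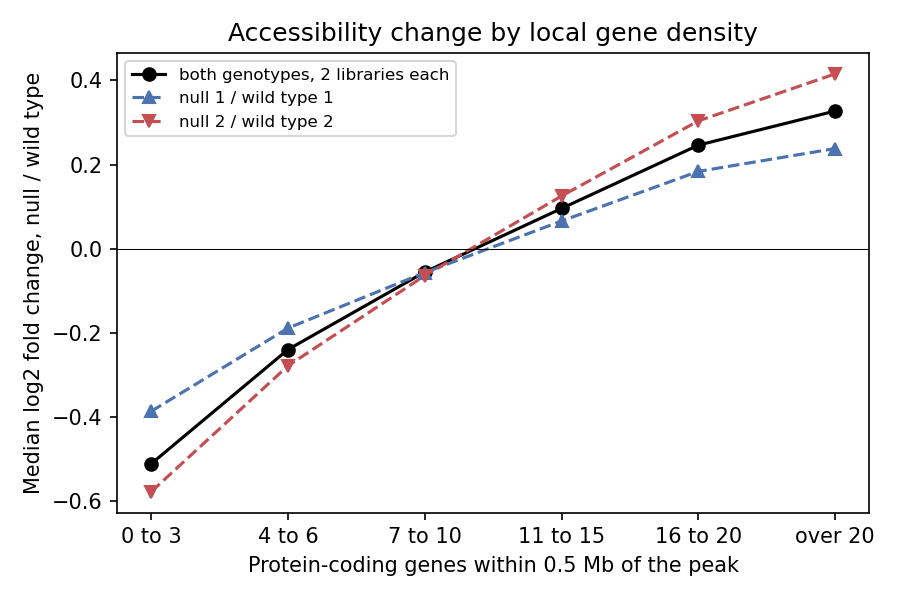
Median log2 fold change of Helios null over wild type by the number of protein-coding genes within 0.5 Mb of the peak. Black points compare both genotypes with 2 libraries each and triangles the libraries of each number; the medians go from -0.51 in the gene-poorest bin to 0.33 in the gene-richest.

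The overall distribution of accessibility was compared per library. Promoter peaks held 35.2 ± 0.817% of counts in wild type and 33.1 ± 0.905% in Helios null (SD, n = 2 each), and distant-promoter peaks 15.99 ± 0.837% and 17.7 ± 0.615%. The most accessible 1% of peaks held 11.2 ± 0.839% and 9.74 ± 0.392% of counts. With 2 libraries against 2, an exact permutation test cannot give a p below 0.333, so these shares are given as values.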

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

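The comparison of the sexes was chosen after sex had been read from the Y-linked counts, and with 1 library per sex and genotype no difference between the sexes was tested. Among the gene lists and the named peaks, 6 results went opposite ways in the libraries of number 1 (male by Y-linked counts) and number 2 (female). The erythroid list had a median log2 fold change of 0.0389 in number 1 and -0.21 in number 2, a difference of -0.248, and the lymphoid list -0.0097 and 0.0067, a difference of 0.0164. In Ikzf2, an intronic peak of low counts (start 69677893) had log2 fold changes of -0.467 and 1.12, a difference of 1.58, and a peak at a transcription end (start 69680599) -0.213 and 0.418, a difference of 0.631. The promoter-class Ikzf2 peaks starting at 69684265 and 69684501 had -0.17 and 0.252 (difference 0.423) and -0.409 and 0.124 (difference 0.533). None of these 6 results passed the test with both libraries of each genotype.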

How the results depend on the processing

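The settings with gene density, equal depth, no chromosome 1, promoter peaks only and DESeq2 with the block were chosen after seeing the data. The number of called peaks (8) ran from 7 to 12 under the other scalings, no filter, autosomes, middle widths, gene density, equal depth and the fold threshold. It was 5 with the stricter filter, which tests fewer peaks, 4 with limma-voom and, in edgeR, 0 without chromosome 1, which holds 7 of the calls (24144 at an unadjusted p under 0.05). Other settings raised the number, and the cause was not tested: 994 with DESeq2, 30595 with the replicate block, 21914 with the replicate block and gene density, 27295 with the replicate block and equal depth, and 8070 with DESeq2 and the replicate block. Leaving out 1 library gave 39 to 27955 calls (39 without Helios null 1, 1021 without wild type 2, 2078 without Helios null 2, 27955 without wild type 1); an arm then has 1 sample, which is assumed to vary like the other group. The replicate number follows sex and, in both genotypes, depth, and same-numbered libraries deviated together with a correlation of 0.335. Of the 18 lists, 9 passed; 0 passed with an estimated correlation, 2 with 1 peak per gene and 3 with promoter peaks only; over 234 settings, single lists kept direction and side in 179, no longer passed in 30, passed in addition in 8 and turned in 17. Of 20 class tests, 0 passed, and 14 with DESeq2 calls (16 against the peaks that DESeq2 adjusted, chosen after seeing the data), 1 with loess offsets and 18 with the replicate block.

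Medians of lists whose camera direction turned were as follows, and the cause was not tested. For gene list erythroid (-0.05): 0.0297 within 10 kb, 0.23 with 1 peak per gene, 0.20 for promoter peaks, -0.017 with total counts, -0.0516 with the replicate block, and -0.20 to 0.0423 without 1 library. For gene list nurd (0.19): -0.0219 with 1 peak per gene, 0.0436 for promoter peaks, -0.0248 with gene density, and 0.047 to 0.23 without 1 library. For gene list lymphoid: -0.21 for promoter peaks and -0.0415 to 0.0328 without 1 library. For gene list hsc, -0.10 with 1 peak per gene; for gene list other_t_nk_cell, -0.14 for promoter peaks and -0.0929 with gene density; for gene list ikaros_family, 0.15 with gene density. Some medians changed sign while the camera direction stayed: for gene list notch -0.0097 with gene density, for gene list other_t_nk_cell -0.0168 and for gene list ikaros_family 0.25 with 1 peak per gene, and for gene list lymphoid -0.0019 with DESeq2 size factors and -0.0093 with loess offsets.

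At Ikzf2 the promoter peak (start 69687010) was -0.78 with the replicate block, -0.72 with the block and equal depth and -0.78 with DESeq2 and the block, and passed in each; without 1 library it was -1.07 to -0.50. Other Ikzf2 peaks turned with gene density, without and with the block: 69683208 (0.17, 0.17), 69684501 (0.35, 0.37), 69688138 (0.29, 0.29), 69688373 (0.13, 0.12) and 69688855 (0.38, 0.38). The peak 69684265 was -0.22 at equal depth and -0.23 with the block as well. Without 1 library, 69684265 ran from -0.14 to 0.21, 69684501 from -0.37 to 0.0604, 69677893 from -0.49 to 1.28 and 69680599 from -0.10 to 0.28. Over the settings, the named peaks kept direction and side of the threshold in 1536 of 2020 values, 463 passed in addition, 4 no longer passed and 17 turned. GC correction, the block with GC correction and motif settings were not run, as no genome was used here; the pseudocount and quantile settings apply to values other than counts and were not run. Libraries thinned to equal depth gave 10 calls. Simulations at the depth of the libraries as deposited found 32% of 2-fold changes at peaks of at least median abundance.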

Other observations

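The tests of explanations in the paragraphs on chromosome 1, on the many small differences and on the megakaryocyte list were chosen after the results were seen, while the replicate block and the estimated correlation were planned. In a principal component comparison of the libraries, the main component held 72.3% of the variance and put both wild-type libraries below both null libraries, with a wide spread inside each genotype. It placed wild type 2 at -179, wild type 1 at -20.8, Helios null 2 at 50.4 and Helios null 1 at 149. Across peaks, which are not independent, its loadings had a Spearman correlation of 0.476 with gene density. The libraries did not group fully by genotype in their Spearman correlations with each other. Wild type 1 correlated more closely with each null library than with wild type 2, while the null libraries correlated most closely with each other. Wild type 2, the library with the fewest counts, had the lowest mean correlation with the others. Chromosome X held 2.04% and 2.61% of counts in the wild-type libraries and 1.63% and 2.01% in the null libraries of the same sex.

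The peaks nearly lost in Helios null gather on chromosome 1, around the targeted gene. The share of these peaks on chromosome 1 was tested after the gathering had been seen (Fisher's exact p = 1.01e-15). That test therefore describes the gathering. It does not decide whether sites across the genome depend on Helios. That p covers only the 20 peaks lost at least 10-fold, not smaller changes. Both Fisher tests of this paragraph count neighbouring peaks as independent. A trend with gene density is argued against, since all 7 called peaks on the chromosome still passed once the trend was removed. A candidate explanation is DNA of another mouse strain linked to the targeted Ikzf2 gene. It was proposed after most lost peaks had been seen on chromosome 1, so the 80% that lie there cannot test it. Within 10 Mb of Ikzf2, 10 of 912 tested peaks were lost, against 6 of 8134 elsewhere on the chromosome (Fisher's exact p = 4.70e-07), the farthest 56.4 Mb away. Strain variants were not examined here, and effects of the deleted gene on its own chromosome stay open.

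The small differences at many peaks are not explained by the trend with gene density alone, since 21914 peaks were still called with the replicate block once it was removed, and 51.8% of the 30595 blocked calls kept their direction and passed. Unequal depth is argued against as the whole cause by 27295 calls in libraries thinned to equal depth. Differences between libraries that do not follow genotype cannot be told apart from genotype, since the 4 libraries can be split in only 3 ways and a share under 0.05 is out of reach. On autosomes the genotype split gave 25678 peaks with an unadjusted p under 0.05. The highest other split, by library number, which follows sex and depth, gave 2130. With the other term in the fit these splits gave 46308 and 26698, and 29398 and 6220 called peaks. An effect of genotype may contribute, as a hypothesis that these 4 libraries do not settle.

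The megakaryocyte and platelet list stayed higher once the trend with gene density was removed (camera adjusted p = 1.36e-04), which argues against that trend as the whole cause. The other lists that rose and passed also still passed then, except the B cell list. The megakaryocyte list also stayed higher without Zfpm1, the gene with many peaks (median 0.27, camera adjusted p = 4.23e-04 over 208 peaks). It therefore does not rest on that gene. More committed erythroid and megakaryocyte progenitors in the sorted cells could raise the list, and this cannot be told apart: the erythroid list had a median of -0.0499 over members that went both ways, and the sort on Lin-Sca1+cKit+ should remove mature cells but not early progenitors. Differences between libraries also stay open, since the rise was not particular to the list. Medians were 0.42 for granulocyte and monocyte, 0.43 for mast cell and basophil and 0.29 for JAK-STAT genes. The list did not pass with an estimated correlation, but neither did a simulated list shifted by 0.5 log2 (camera adjusted p = 0.11). That setting therefore does not decide. An effect of genotype stays open as a hypothesis, and subsets of stem cells were not told apart here.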
